A study of Homo sapiens with 4 samples.

How the data were processed

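The series holds 4 libraries of MDA-MB-231 cells, 2 from immunoprecipitation with an anti-SRPK2 antibody after UV crosslinking and 2 matched inputs. Per the labels' protocols, libraries were made with a KAPA RNA kit and sequenced in pairs of 150 bases. Per the submitters' processing notes, bcl2fastq and TopHat2 were used and positions are on GRCh38; versions, the peak caller and the annotation release are not given in the sources used here. Groups and replicate numbers came from the sample titles.

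The analysis started from 1 peak list per IP library, each called by the authors against the input of the same number. Per the file headers, each peak has the counts of IP and input reads, deposited as whole numbers. The RPKM of both libraries was computed by the authors, and the deposited values equalled the reads divided by the length of the peak and by the total reads of the library on the usual scale, which gave back the library totals. The authors' log2 fold equalled log2 of (IP RPKM + 1) over (input RPKM + 1) in each row; it was recomputed and used to describe and rank peaks within a list. It differs from a plain ratio of reads where the RPKM is low. The authors' deposited p-value per peak is not adjusted. It followed the 2 read counts with depth ratios of 1.38 and 1.53, whereas the RPKM totals gave 1.20 and 1.27, and it was used only to take the stronger part of a list and as an alternative. In the authors' deposited table, 687 and 883 peaks had a p under 0.05. The deposited signal, the highest read depth over a peak, served as peak height in an alternative. The feature class and the share of each peak in coding sequence, untranslated region, noncoding exon and intron are the authors' calls, per the file headers; 17 and 26 peaks assigned to an exon had all of their bases in an intron. All rows had a log2 fold of at least 1 and at least 10 IP reads, and positions are 1-based. Input reads were used only within listed IP peaks, so levels of RNA outside them are unknown.

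Each peak was tested with a two-sided exact binomial test of IP against input reads, given the RPKM library totals, with Benjamini-Hochberg adjustment over the list. Folds at peaks with few reads are ratios of depth-scaled reads with exact 95% counting intervals, and an input of 0 was replaced by a floor of 3 reads. Shares have Wilson intervals. Peaks were called shared at an overlap of at least 1 base on the same strand, and 1000 random placements in the same gene gave the expected number. Gene spans came from a table of RefSeq genes on GRCh38.p14, matched by symbol or synonym for 2037 of 2118 symbols (96.2%). Genes in both lists and gene lists were tested with two-sided Fisher's exact tests against 38386 genes, 20056 protein-coding and 18330 long noncoding. Gene-level results used sense peaks; antisense peaks were kept apart. Correlations had 100000 permutations. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used.

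Plans for shared peaks, shared genes, feature shares, gene lists and peak strength, and the 19 gene lists, were fixed before the data were examined. The binomial test of peaks against input, the tests of shared pairs above input and the border peaks were not part of them. Neither was the comparison of feature shares between the lists, nor the alternatives marked below as added. With 2 libraries, each one's value is given, and a mean and SD where the design planned them. Named genes were, by a fixed rule, the 20 with the highest mean rank of their strongest shared peak by fold, the 10 with the most shared peaks, up to 4 members with a shared peak of each gene list, and SRPK2 with the SR proteins and SR protein kinases that had a peak. Some genes that the rule names are not reported here. HNRNPC, MVD, CD44, THBS1, NEAT1, PLEC, CH507-513H4.1, CH507-528H12.1 and the small RNAs named stand outside that rule and were chosen after their values were seen.

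Placement was tested on simulated data. With no shared peak planted, 95 of 2184 placed peaks had a partner against 107 expected (permutation p = 0.905); with 200 planted, 276 had one (permutation p = 0.005, the smallest that test could give). The binomial test, on 2267 and 3029 simulated peaks, made 1 and 1 false calls and found 4% and 7% of 100 peaks changed 2-fold, and 47% and 66% of 100 changed 4-fold. All other simulated peaks were left unchanged, unlike the lists, where each row had a log2 fold of at least 1. The list test called 0 of 200 random lists and 100% of lists with 6 planted members. The placement and list simulations drew peaks inside gene spans, and genes from the whole background, at random as the tests assume. They check the computation only. They do not cover peaks held to exons or genes at unlike RNA levels.

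Distances to splice sites and peak sequence composition were planned but not run, because no exon models or genome sequence were used here; peaks reaching over an exon border, by the authors' base shares, stand in for the first. Placement within the same feature class was not run for the same reason. The authors' calls replaced the midpoint assignment to features, and no placement test of features was made. The planned lists of small structural and mitochondrial RNAs had no member in the background of the list test.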

Results

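The kinase SRPK2 phosphorylates the serine- and arginine-rich domains of splicing factors. RNA recovered by its immunoprecipitation was profiled in MDA-MB-231, a triple-negative breast cancer cell line. Cells were UV-crosslinked, RNA was recovered with an antibody against SRPK2, and 2 immunoprecipitation (IP) libraries were each compared by the authors with an input library of the same replicate number. The design asks which RNAs SRPK2 contacts and where on them. The series holds no IP with a control antibody or from cells lacking SRPK2, so enrichment over input cannot be credited to SRPK2 alone. The deposited lists held 2267 peaks for IP library 1 and 3029 for IP library 2, called per library and not on pooled reads. The RPKM values implied 2228553 and 2411172 reads for the IP libraries and 1849823 and 1902014 for the inputs. Listed peaks had a median length of 301 and 286 bases and a median of 13 and 14 IP reads against 4 and 4 input reads, and they took 2.37% and 5.79% of the IP reads. All intervals below cover counting error only, since reads made by PCR are not independent molecules. At 201 intervals that overlapped by at least 90% in both lists, the IP libraries held 9132 and 11395 reads, a ratio of 1.25 against 1.08 for the library totals. Once that ratio was fitted, the remaining scatter was within sampling noise (chi-square 166, p = 0.961). These intervals were chosen because both lists called them alike, so this does not decide whether the libraries are separate samples, and they were kept as n = 2. Nothing in the labels names separate cultures, so no p-value here measures the spread between cultures. P-values of tests on reads reflect counting error only. Those for overlaps, feature shares, gene lists and correlations take peaks, genes or chromosomes as units, so they do not measure the spread between libraries. Only the comparison of RPKM at shared pairs, given further below, uses that spread.

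FASN, the fatty acid synthase, had 10 shared sense peaks that passed the test against input in both libraries, more than any other gene. Its strongest shared peak, in coding exon sequence on chromosome 17 from 82084513 to 82084721 (GRCh38, minus strand), held 140 IP reads against 41 input reads in IP library 1, a log2 fold of 1.49 (adjusted p = 4.98e-08, two-sided exact binomial test). In IP library 2 it held 172 against 39 reads, a log2 fold of 1.79 (adjusted p = 5.07e-13, exact binomial test). An antisense peak lay over this same place in both libraries. It held 57 against 11 reads in library 1 (log2 fold 2.07) and 56 against 15 in library 2 (1.53), so the signal there was not limited to the sense strand. AGRN, which encodes the extracellular matrix proteoglycan agrin, had 104 against 25 reads and 136 against 37 reads in coding exon sequence on chromosome 1 from 1044110 to 1044263 (log2 folds 1.78 and 1.53). PKD1, which encodes polycystin, had log2 folds of 1.45 and 1.68 from 49 against 14 and 88 against 20 reads. Over all listed peaks, 430 of 2267 (18.97%) in library 1 and 800 of 3029 (26.4%) in library 2 passed an adjusted p of 0.05 against their own input. The test compares those libraries' reads, not conditions, and every listed peak had already been kept by the authors at a log2 fold of at least 1 and at least 10 IP reads. On simulated reads at these depths the test found 4% and 7% of 2-fold and 47% and 66% of 4-fold changes. Most simulated peaks were left unchanged, which makes the adjustment stricter than in these lists, so those shares do not give the power here. Most listed peaks did not pass singly.

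Annotated exons held most of the peaks, and the strand opposite to the gene held the next largest class. By the authors' assignment, exons held 77.3% of peaks in library 1 (95% Wilson interval 75.6 to 79.0) and 69.7% in library 2 (68.0 to 71.3). Introns held 5.78% (4.89 to 6.82) and 7.86% (6.95 to 8.87), and intergenic sequence 1.24% (0.856 to 1.78) and 1.02% (0.722 to 1.45). Antisense peaks numbered 355 (15.7%, Wilson interval ± 1.50) and 649 (21.4%, ± 1.46). Over both lists exon peaks averaged 73.5% ± 5.40 (SD, n = 2) and antisense peaks 18.5% ± 4.08 (SD, n = 2). The exon, intron and antisense shares differed between the lists (two-sided Fisher's exact test with Benjamini-Hochberg adjustment, adjusted p = 0.00429 for introns and 2.07e-07 for antisense), and the intergenic share was not shown to differ (adjusted p = 0.509). Within sense peaks, coding sequence made up 53.5% ± 1.23 of bases (mean ± SD over both lists, n = 2), 3′ untranslated regions 17.2% ± 2.29, introns 18.4% ± 3.46, noncoding exons 5.70% ± 0.314 and 5′ untranslated regions 5.25% ± 0.374. Peaks reaching from an exon into an intron made up 52.7% and 51.3% of sense peaks, but 20.9% ± 0.0750 (SD, n = 2) when at least 10% of the peak had to lie on each side.

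**Figure D1:**
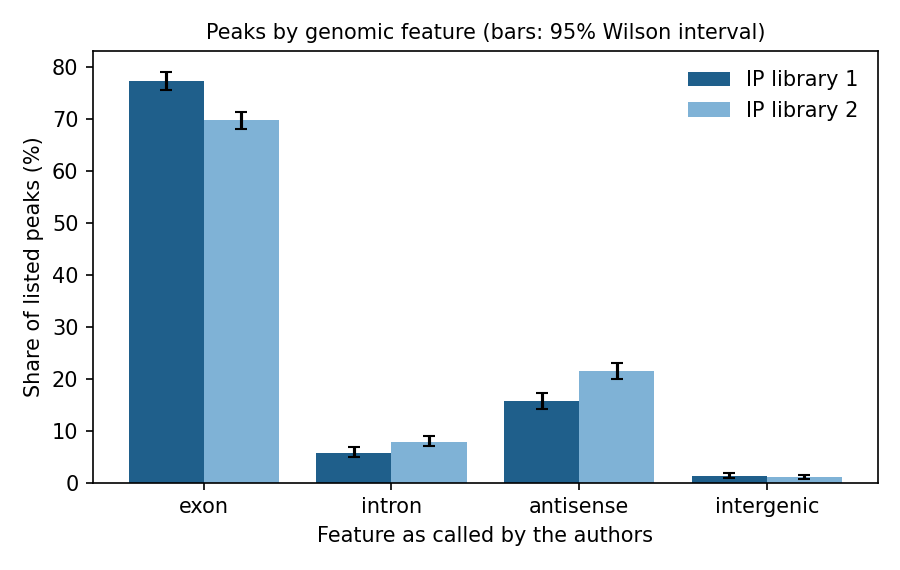
Share of listed peaks (%) by the feature the authors assigned, for each IP library; error bars are 95% Wilson intervals. Exons hold 77.3% and 69.7% of peaks, and the antisense strand 15.7% and 21.4%.

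PIEZO1, which encodes a mechanosensitive ion channel, had the most sense peaks at the same place in both lists, 14 pairs. It was followed by HSPG2, the basement membrane proteoglycan perlecan, with 11 pairs, FASN with 10, AGRN with 9 and HELZ2 with 8. LAMA5, which encodes a laminin chain of basement membranes, and PKD1 each had 7 pairs, TNRC18 had 6, and CIC, a transcriptional repressor, and SCRIB, a cell polarity scaffold, had 5. These 10 genes held 82 of 394 sense pairs (20.8%). All 10 pairs in FASN passed an adjusted p of 0.05 in both libraries (exact binomial test), with log2 folds from 1.15 to 1.59 in library 1 and from 1.05 to 1.79 in library 2. AGRN and HELZ2 had 6 pairs each that passed in both, PKD1 4, LAMA5 3, and CIC and SCRIB 1 each. PIEZO1, HSPG2 and TNRC18 had 2 each. Outside these genes PLEC had 4 such pairs. Over all genes and strands 112 of 517 pairs in 49 genes passed in both. Of these pairs, 74 were sense, 36 antisense and 2 intergenic.

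**Figure D2:**
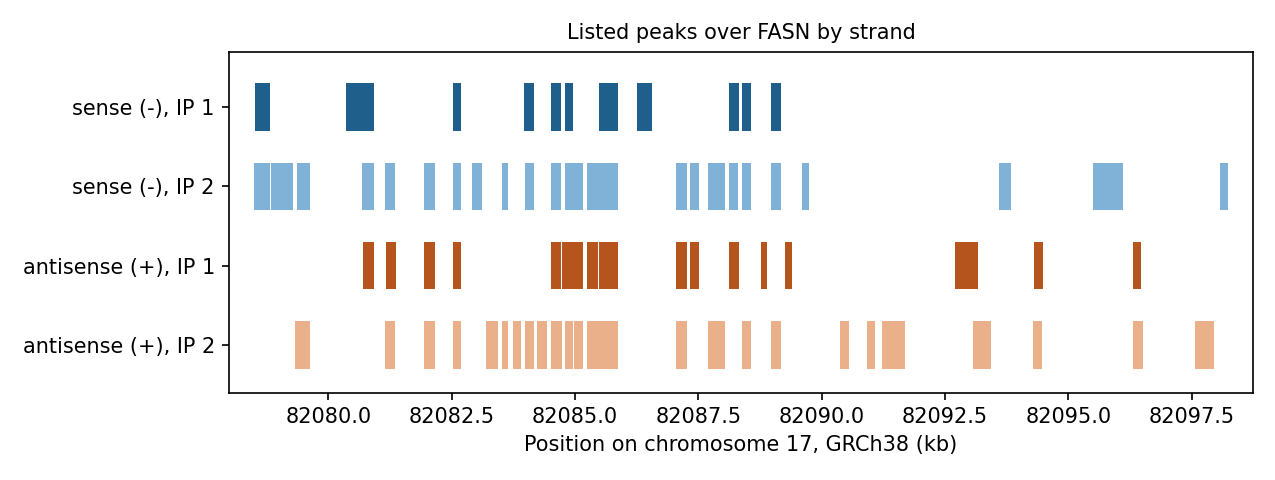
Position of each listed peak over FASN on chromosome 17 (GRCh38, kilobases), by strand and IP library; each block spans a peak. The 11 and 23 sense peaks and the 16 and 24 antisense peaks lie between positions 82078493 and 82098234.

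Shared positions were counted with at least 1 base of overlap on the same strand. Peaks of library 1 had a partner in 507 of 2267 cases (22.4%, 20.7 to 24.1), and peaks of library 2 in 507 of 3029 (16.7%, 15.5 to 18.1). Among the 2184 peaks of library 1 whose gene had a known span, 482 had a partner, against a mean of 108 when they were placed at random in the same gene, a ratio of 4.45 (permutation p = 0.001, the smallest that 1000 placements can give). Gene spans include introns, whereas most peaks were exonic. With each gene shortened to an assumed exonic territory of at most 5000 bases, the ratio was 0.95 (permutation p = 0.966) at 1 base of overlap and 1.93 (permutation p = 0.001) when 50% of both peaks had to overlap. In genes such as HSPG2, with 41 sense peaks in library 2 and a median peak of 286 bases in that list, peaks can fill 5000 bases. A partner by chance is then very likely, so 0.95 cannot show that the excess is absent.

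**Figure D3:**
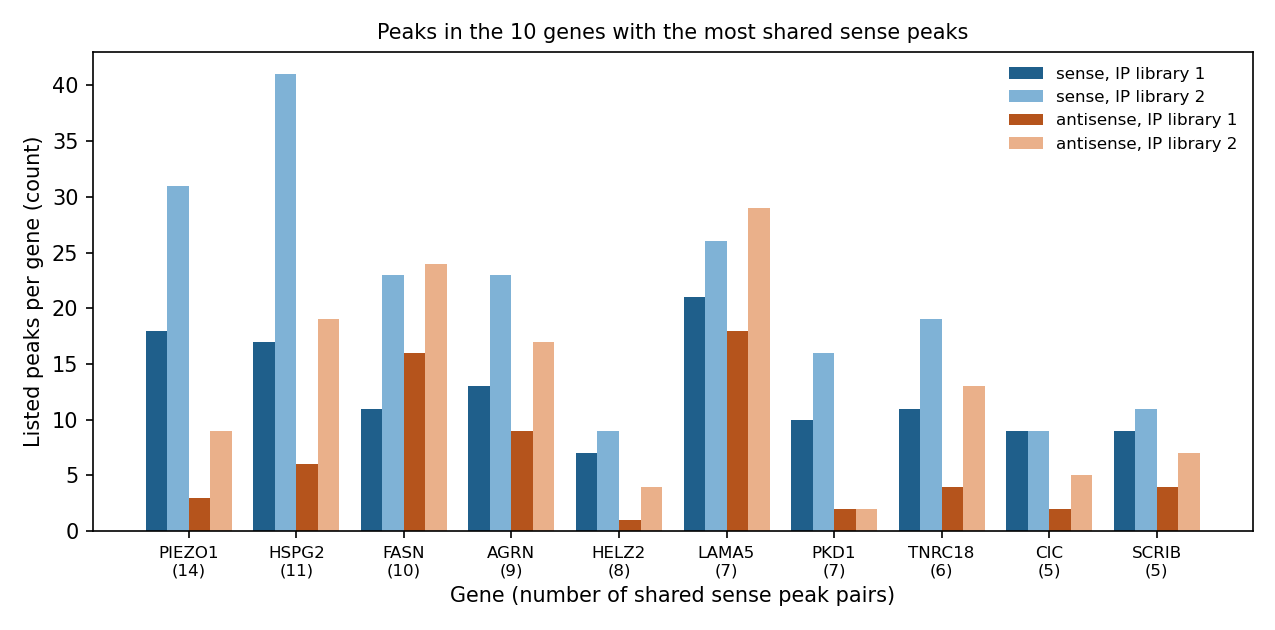
Number of listed peaks per gene in the 10 genes with the most shared sense peaks, by strand and IP library; the number of shared sense pairs stands in brackets. HSPG2 has 17 and 41 sense peaks, and LAMA5 has 18 and 29 antisense peaks.

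The largest folds at shared positions lay in peaks with few reads. GARS1, the glycyl-tRNA synthetase, had 11 IP reads against 1 input read in library 1 (9.13-fold, 95% counting interval 1.33 to 393) and 10 against 1 in library 2 (7.89-fold, 1.12 to 342), in an exon on chromosome 7 from 30622319 to 30622469. The long noncoding RNA DANT2 had 11 against 1 and 14 against 1 reads in an intron (9.13-fold, 1.33 to 393, and 11.04-fold, 1.68 to 467). OSBPL8, an oxysterol-binding protein, had 12 against 1 and 17 against 2 reads in an intron (9.96-fold, 1.47 to 426, and 6.71-fold, 1.59 to 59.8). HSPG2 had 11 against 2 reads in library 1, and 11 against 0 in library 2. The latter was 2.89-fold with the input set to a floor of 3 reads, a value without a counting interval. KNL1, a kinetochore scaffold, had 12 against 2 reads and 10 against 0, the latter 2.63-fold with the same floor and without a counting interval. INTS1, an Integrator subunit, stood on more reads, 23 against 3 and 43 against 8 (6.36-fold, 1.92 to 33.1, and 4.24-fold, 1.97 to 10.4). The other genes with the highest ranks were MICALL2, CSNK1D, RAB11FIP3, DYNC1H1, MRC2, LTBP2, CCDC57, ITGA6, MYO18A, FN1, FLNC, INPPL1, CIC and ARHGAP35.

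Over the 517 pairs, the log2 folds of the 2 libraries were not shown to be related (Spearman's rho 0.08, permutation p = 0.0795, adjusted p = 0.119; Pearson's r 0.08, permutation p = 0.0775). Levels of IP reads per kilobase were related closely (Spearman's rho 0.88, Pearson's r 0.92, permutation p = 1e-05 each, the smallest that 100000 permutations can give). Among 51 pairs with at least 50 IP reads in both libraries, rho for the folds was 0.18 (permutation p = 0.194). These 3 correlations are across peaks, which are not independent replicates. The relation of the folds passed its threshold, at rho 0.10, when 50% of both peaks had to overlap (permutation p = 0.0454).

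**Figure D4:**
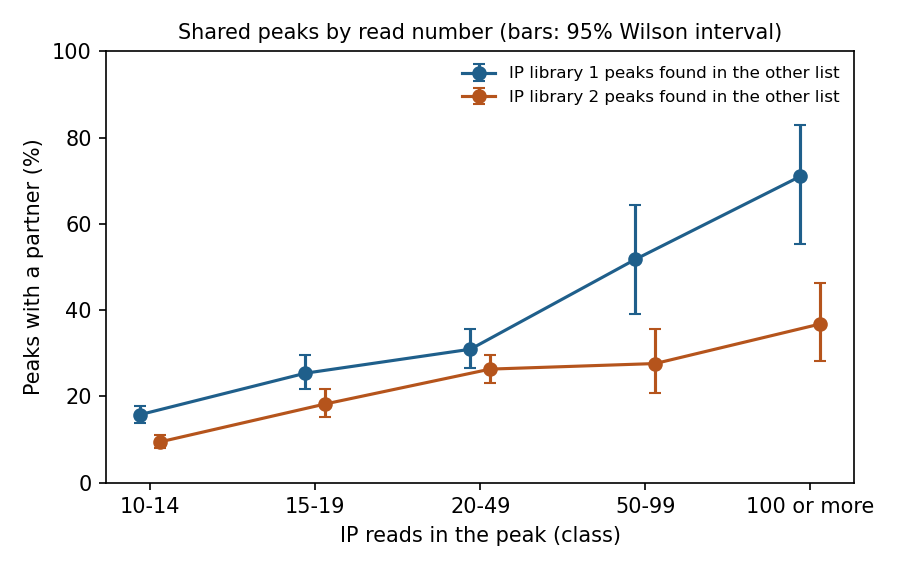
Share of peaks (%) with a partner in the other list, by the number of IP reads in the peak; error bars are 95% Wilson intervals. In library 1 the share is 15.8% at 10 to 14 reads and 71.1% at 100 or more, and in library 2 it is 9.44% and 36.8%.

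Sense peaks lay in 1177 background genes in library 1 and 1274 in library 2, and 551 genes were in both, among them FASN, AGRN, PIEZO1 and LAMA5. Independent lists of these sizes among 38386 protein-coding and long noncoding genes would share 39.1 genes, a ratio of 14.1 and an odds ratio of 44.4. The p of Fisher's exact test was below the smallest number that could be stored. Levels of RNA are not known from peak lists, so genes too low to yield a peak stayed in the background. Genes with at least 2 sense peaks in each list numbered 161.

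Of 17 gene lists tested, 4 passed an adjusted p of 0.05, with shared sense peaks above the 0.664% share of all background genes. Among hnRNP proteins, abundant nuclear RNA-binding proteins, 5 of 24 genes had one (HNRNPC, HNRNPD, HNRNPH1, HNRNPH3 and PCBP1; odds ratio 40.1, adjusted p = 4.05e-06, Fisher's exact test with Benjamini-Hochberg adjustment). Among mesenchymal and extracellular matrix genes it was 6 of 44 (CD44, FN1, ITGA6, ITGB1, LAMB1 and THBS1; odds ratio 24.2, adjusted exact p = 4.05e-06). Among lipid synthesis enzymes and their regulators it was 5 of 35 (among them DHCR7, FASN and MVD; odds ratio 25.4, adjusted exact p = 1.94e-05), of which DHCR7 and MVD act in cholesterol synthesis. Among cell cycle genes it was 3 of 48 (CENPF, MKI67 and TOP2A; odds ratio 10.1, adjusted exact p = 0.0171). Every other list with a shared sense peak also lay above 0.664%, from 2.33% for housekeeping mRNAs to 7.14% for SR proteins, without passing. Against genes with a peak in at least 1 list as background, 0 of 16 lists passed Fisher's exact test, with adjusted p from 0.332 upwards. There 2 lists had an unadjusted p under 0.05. Against random lists matched on gene length the cell cycle list did not pass (adjusted permutation p = 0.19). With the genes of a single library, 11 lists passed without library 1 and 11 without library 2.

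Members of these lists spanned a range of folds at their strongest shared peak. In the 4 passing lists, only FASN had a shared sense peak that passed an adjusted p of 0.05 in both libraries (exact binomial test). ITGA6, an integrin chain, had 13 against 2 and 10 against 2 reads (5.40-fold, 1.22 to 49.2, and 3.94-fold, 0.841 to 37.0). PCBP1 had 22 against 8 and 62 against 18 reads (log2 folds 1.08 and 1.32), DHCR7 14 against 4 and 11 against 4 (1.33 and 1.04), and MKI67 21 against 6 and 29 against 8 (1.45 and 1.45). FN1, the matrix protein fibronectin, had 13 against 3 and 21 against 3 reads (3.597-fold, 0.988 to 19.7, and 5.52-fold, 1.65 to 28.9). Of the sense peaks in lipid synthesis genes, 12 of 37 in library 1 and 27 of 49 in library 2 passed an adjusted p of 0.05 over all peaks, and 13 and 31 when adjusted over the list alone. FASN held most of these passes, 11 of its 11 and 21 of its 23 peaks; in the other lipid genes 1 of 26 and 6 of 26 passed over all peaks. For mesenchymal and matrix genes these counts were 6 of 38 and 10 of 48 over all peaks, and 15 and 10 adjusted over the list alone. For hnRNP genes they were 2 of 14 and 2 of 10 either way, and for cell cycle genes 2 of 17 and 2 of 22 over all peaks and 2 and 0 adjusted over the list alone.

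**Figure D5:**
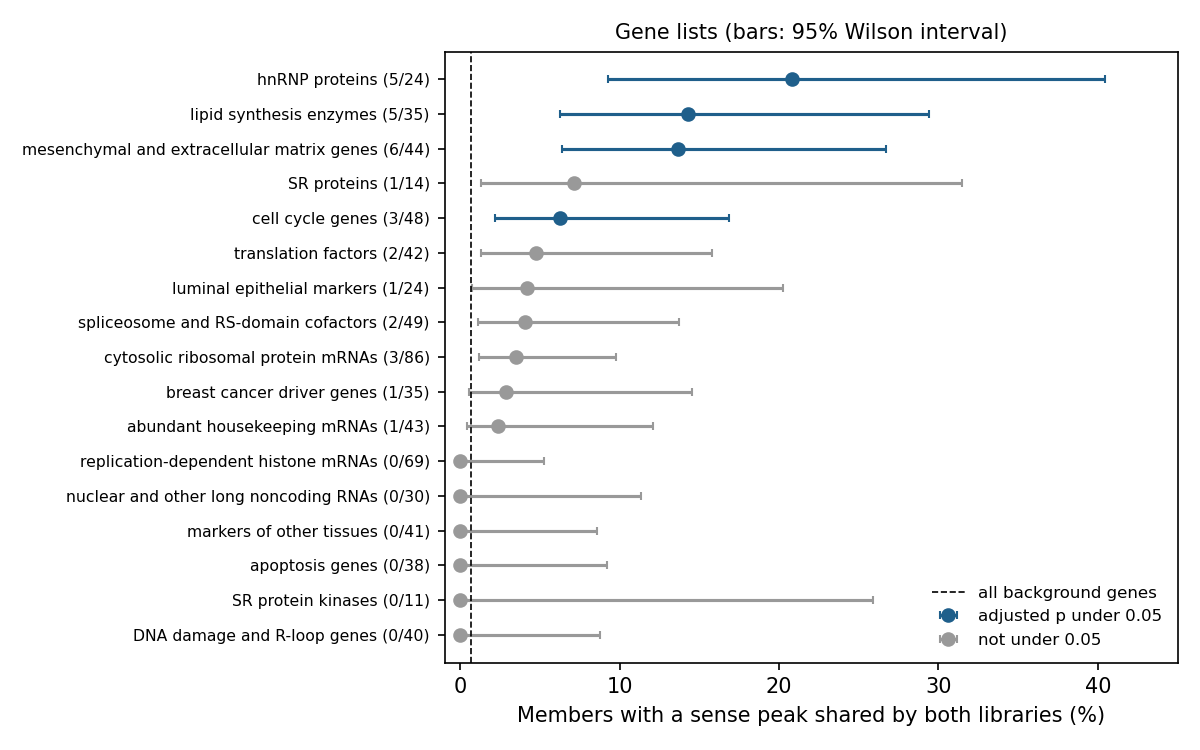
Share of members (%) with a sense peak shared by both libraries for the 17 tested gene lists; error bars are 95% Wilson intervals and the dashed line is the 0.664% of all background genes. The points for hnRNP proteins, lipid synthesis enzymes, mesenchymal and extracellular matrix genes and cell cycle genes are those with an adjusted p under 0.05.

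SR proteins, the known substrates of SRPK kinases, had 4 sense peaks in library 1 and 5 in library 2. Only SRSF11 of 14 members had a shared peak, in coding exon sequence on chromosome 1 from 70250363 to 70250508, with 10 against 4 and 12 against 2 reads (2.08-fold, 0.599 to 9.06, and 4.73-fold, 1.05 to 43.5), and the list did not pass (adjusted p = 0.189, Fisher's exact test). With the genes of a single library it did pass, at 4 of 14 without library 1 (adjusted exact p = 0.00143) and at 3 of 14 without library 2 (adjusted exact p = 0.0126). SRSF6 and TRA2B had a sense peak in library 1 only, and SRSF1, SRSF4 and SRSF10 in library 2 only. Of these, SRSF10 passed on its own with 25 against 5 reads (log2 fold 1.80, adjusted p = 0.0186, exact binomial test). No peak was listed on SRPK2 itself. Its relative SRPK1 had 3 sense peaks in library 1 only, the strongest with 16 reads against 1 (13.3-fold, 2.06 to 557, adjusted p = 0.0144, exact binomial test). SRPK3 had 2 in library 2 only, and PRPF4B 1 in library 1 only, so that 0 of 11 SR protein kinase genes had a shared peak, with 0.0731 expected.

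Spliceosome proteins and RS-domain cofactors had shared peaks in 2 of 49 genes, BCLAF1 and SRRM1 (adjusted exact p = 0.102). Translation factors had 2 of 42, EIF1 and EIF4G1 (0.0901), cytosolic ribosomal proteins 3 of 86, among them RPL14 and RPS4X (0.0673), and abundant housekeeping mRNAs 1 of 43, ANXA2 (0.385). Luminal epithelial markers had 1 of 24, MUC1 (adjusted exact p = 0.279), and breast cancer driver genes 1 of 35, EGFR (0.354). Without position compared, the spliceosome list passed at 6 of 49 genes (adjusted exact p = 0.00024). The translation, ribosomal protein, housekeeping and driver lists passed in that setting too. With the genes of either library alone all of these lists passed, whereas luminal markers passed in none of these settings. None of 30 long noncoding RNAs, 38 apoptosis genes, 40 DNA damage and R-loop genes or 69 histone genes had a shared peak. At the background share 0.199, 0.252, 0.266 and 0.458 genes would have had one, so these zeros do not show absence. No marker of other tissues of 41 had a sense peak in either list. Sense peaks of NEAT1, a nuclear long noncoding RNA, were in library 1 only, 2 in number. Of 2439 genes in the list of small structural RNAs, which left out ribosomal RNA, 2 had a listed peak, SNORD41 and SNORD62B, and no mitochondrially encoded RNA had one; both lists stayed outside the test.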

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

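The random lists matched on gene length and the list tests without position compared or with a single library were planned; the other tests in this part were chosen after the results they concern were seen. Peaks outside the sense strand of genes entered no gene-level comparison, yet many stood above their input. Antisense peaks with an adjusted p under 0.05 numbered 77 in IP library 1 and 188 in IP library 2 (exact binomial test), and intergenic peaks 12 and 11. The share of antisense peaks that passed was 21.7% and 29.0%, against 17.7% and 25.8% of exon peaks and 23.7% and 23.5% of intron peaks.

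The first pattern is the antisense class. FASN had 16 and 24 antisense against 11 and 23 sense peaks, and LAMA5 18 and 29 against 21 and 26, but PIEZO1 had 3 and 9 against 18 and 31, and PKD1 2 and 2 against 10 and 16. A partial loss of strand information may be involved: antisense peaks lay over a sense peak of the same library 4.51 times as often as random placements in the gene in library 1 and 3.19 times in library 2 (permutation p = 0.001 each, the smallest that 1000 placements can give), and median antisense over sense RPKM at those places was 0.602 and 0.517 in the IP and 0.472 and 0.449 in the input. With genes shortened to an assumed 5000 bases the ratios were 0.839 and 0.794, so the excess depends on the span assumed. Such a span is short for genes with many peaks, so neither set of ratios decides the question. Genomic DNA carried into the libraries and RNA transcribed from the opposite strand stay open, since only intervals enriched over input are listed, and no biological explanation was tested.

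The second pattern is that most peaks of each list lacked a partner in the other. Few reads per peak are a candidate explanation, since 71.1% of library 1 peaks with at least 100 IP reads had a partner (55.2 to 83.0) against 15.8% with 10 to 14 reads (13.9 to 17.9), and 36.8% against 9.44% in library 2. Folds close to the authors' limit could add to it in library 2, where among peaks with at least 50 reads 17.05% with a log2 fold under 1.2 had a partner (10.6 to 26.2) against 45.3% at 1.3 or more (36.1 to 54.8). In library 1 the shares were 56.1% and 57.9% with overlapping intervals, on 41 and 38 peaks, too few to decide. No biological explanation was tested.

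The third pattern is the excess of shared peaks in 4 gene lists. The hnRNP proteins, lipid synthesis enzymes and mesenchymal and extracellular matrix genes stayed above random lists matched on gene length and biotype (adjusted permutation p = 0.00227, 0.00227 and 0.00227). The random lists were drawn from all background genes, whether or not their RNA was present. Exonic length was not matched, for lack of exon models. For these 3 lists the values argue against gene length alone, but not against exonic length or length together with RNA level. For cell cycle genes length stays open (adjusted permutation p = 0.19). RNA abundance alone could not be decided. The 4 lists together had shared peaks in 19 of 151 genes (12.6%) and abundant housekeeping mRNAs in 1 of 43 (2.33%), with p = 0.0831 in Fisher's exact test. The 4 lists were picked because they had passed on these same data, so this comparison cannot decide the question. Against genes with a peak in at least 1 list, 0 of 16 lists passed Fisher's exact test after adjustment. Without position compared, the housekeeping list did pass, at 4 of 43 (odds ratio 7.09, adjusted exact p = 0.00943). It passed in single libraries too, at 12 of 43 each, with odds ratios of 11.4 without library 1 and 12.4 without library 2, against 12.06 and 37.8 for hnRNP proteins. Levels of genes without peaks are unknown. No biological explanation was tested.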

How the results depend on the processing

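Settings marked as added here were chosen after seeing the data: the 5000-base territory, antisense peaks left out or counted, the short arm of chromosome 21 left out, protein-coding genes for the list test, and all settings for border peaks, for peaks above input and for shared pairs above input. The excess of shared peaks kept its direction and threshold under 6 of 7 alternatives. Ratios lay between 3.84 and 11.9 over gene spans and were 1.93 in the territory at 50% overlap. At 1 base in the territory the ratio fell to 0.95, where shorter genes raise the chance overlap. Every setting over gene spans placed mostly exonic peaks over introns too. Those settings therefore do not check whether exonic position alone gives the excess. The stronger peaks of each list by the authors' p shared 216 peaks in place of 507 and 231 genes in place of 551, since fewer peaks entered. The odds ratio of genes in both lists lay between 22.8 and 168 over its alternatives. Exon peaks averaged 73.5% and were 72.3% among the stronger peaks, 67.0% by bases, and 69.7% to 77.3% without 1 library; antisense peaks averaged 18.5% and were 19.9%, 16.0%, and 15.7% to 21.4%. The 4 passing gene lists became 0 against genes with a peak, 9 when position was not compared, and 11 to 11 without 1 library. Against protein-coding genes 3 passed, with odds ratios of 21.2 for hnRNP proteins, 13.4 for lipid synthesis and 12.7 for matrix genes, and cell cycle genes missed the threshold (5.31, adjusted exact p = 0.0941). Without 1 library, DNA damage genes went from an odds ratio of 0 to 2.57 to 7.32, passing only without library 1 (adjusted exact p = 7.31e-05, against 0.150), and apoptosis genes from 0 to 3.43 to 4.81, passing only without library 2 (adjusted exact p = 0.00990, against 0.0517). Border peaks averaged 52.0%, and 20.9% with 10% on each side. Agreement of folds, at rho 0.08, passed its threshold at 50% overlap (0.10); other measures of strength, peak height (0.88) and the authors' −log10 p (0.43), passed too. Peaks above input numbered 430 and 800 by the adjusted binomial test, 1052 and 1676 unadjusted, 115 and 253 by the authors' deposited p after adjustment, and 687 and 883 before. For these differences the cause was not tested, apart from fewer peaks or another background by construction. Of the settings for single gene lists, 93 changed no call and 6 ended a call. In 17 a list came past the threshold in the same direction. The remaining 2 were those passes of DNA damage and apoptosis genes. Both had started from 0 shared genes with 0.266 and 0.252 expected, which is no sign of depletion. The overlap tests have no replicate block. At the 517 shared pairs, 112 of which passed in each library singly, tests over both libraries were added. The summed reads passed at 513 pairs without and 513 with the replicate block (adjusted exact test), where the authors' limits had already kept only folds of at least 2 in each list. A t-test of log2 RPKM passed at 84 without the block and at 0 when paired, with 1 degree of freedom. IP and input libraries of the same number deviated together (r 0.45). Both were read over the same interval, and only 17 of the 517 pairs had identical intervals in the 2 lists. A positive r can therefore come from the intervals alone. With 2 pairs of libraries and labels that give only a number, it does not show that the numbers pair them. Depth limits single peaks, but by how much in these lists is not known. On simulated reads with most peaks unchanged, the binomial test found 4% and 7% of 2-fold changes.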

Other observations

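Ribosomal DNA on the short arm of chromosome 21 took a large part of the reads in peaks. Between positions 8207641 and 8440639, over the long noncoding genes CH507-513H4.1 and CH507-528H12.1 and copies of 5.8S ribosomal RNA, 17 peaks in IP library 1 and 32 in IP library 2 held 21.4% and 44.7% of all IP reads in peaks. They covered 5.30 and 14.8 kilobases and held 0.509% and 2.59% of the IP libraries. The inputs had 25.3% and 48.4% of their reads in peaks there, and median log2 folds were 1.46 and 1.32. Such genes have near-identical copies, so reads cannot be assigned to 1 copy. PLEC, which encodes the cytolinker plectin, held 570 and 8969 IP reads against 224 and 3215 input reads in 6 and 20 sense peaks.

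Protein-coding genes with a sense peak were unevenly spread over the chromosomes. On chromosome 19 they made up 7.86% and 10.3% of genes in the 2 libraries, on chromosome 20 8.19% and 8.19%, and on chromosome 17 7.10% and 8.13%, against 2.37% and 3.85% on chromosome 13 and 3.42% and 3.54% on chromosome X. Over 23 chromosomes the mean share rose with the number of protein-coding genes per megabase (Pearson's r 0.70, permutation p = 2e-05, adjusted p = 4e-05; Spearman's rho 0.69, permutation p = 0.00046, adjusted p = 0.00046). Without chromosomes 19 and 17, the farthest from the median density, r was 0.61 (permutation p = 0.00337) and rho 0.59 (permutation p = 0.00522). This relation was looked for after the chromosome values were seen.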
